A study of Homo sapiens with 18 samples.

How the data were processed

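RNA was measured by sequencing in 18 libraries of human embryonic stem cells, from the established lines H1 (WA01) and H9 (WA09). Per the labels, total RNA was extracted with TRIzol, polyadenylated RNA was enriched, and libraries were made with the NEBNext Ultra II kit. The labels give clone 1-5 of H1 as a heterozygous knockout of ZNF263 and clones 1-10 of H1 and 9-1 and 9-D of H9 as homozygous knockouts made with Cas9. They do not state the edited part of the gene, whether the replicates of a group were separate cultures, or any date or batch.

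The deposited count tables hold whole read counts for 27130 gene symbols in each library. Per the submitters' processing notes, reads were aligned with STAR to hg19, counted with featureCounts and compared with DESeq2, and no version or option is given. Per the file headers, the authors' deposited comparison tables hold a log2 fold change of knockout over wild type and a p-value adjusted by DESeq2 for each gene. In the count tables, columns named by cell line and number alone were taken as the wild-type replicates with those numbers, and the column named as a control as the single wild-type library. Symbols are used as the files give them. Of these, 25687 matched a gene of the RefSeq GRCh38.p14 annotation, 24340 by symbol and 1347 by an older name. That assembly differs from the one used for counting, so no coordinates are printed and the annotation served for names, chromosomes and neighbouring genes only.

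Library totals ranged from 9.66 to 21 M counts. The limit that a count of 0 allows was set at 3 counts, and over a group this limit was applied to the summed counts. Folds against a group at 0 are lower bounds against that limit. Where the lower group held 1 to 3 counts, the ratio of summed counts per library total is given with its exact 95% counting interval. Intervals of shares are exact Clopper-Pearson intervals. Limits and intervals cover counting error only, since reads were not marked by molecule. Between replicates of a group, chi-square per gene ranged from 1.83 to 5.97 over 15 pairs of libraries, so replicates varied more than counting error gives.

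The main test was edgeR's quasi-likelihood F test (version 4.0.16, R 4.3.3) on the counts, with TMM scaling, filterByExpr by group, Benjamini-Hochberg adjustment and a threshold of 0.05 on adjusted p. The comparisons were H1 clone 1-10 against H1 wild type (3 and 3 libraries), both H9 clones together against H9 wild type (6 and 3), each H9 clone against H9 wild type and against the other in a model of 3 groups, and the difference of the knockout effects in H9 and H1 over 15 libraries. Standard errors (SE) of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, scaled within each comparison. Log2 fold changes were knockout over wild type, or 9-D over 9-1. Gene symbols of XIST and Y-linked genes entered the tests and are not listed.

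Gene lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists with at least 5 tested members, and again with a correlation estimated from the residuals. The 28 lists were core, primed and naive pluripotency; primitive streak and mesendoderm; definitive endoderm; mesoderm; neuroectoderm and neurons; neural crest; trophoblast and amnion; fibroblast and feeder; NODAL and TGF-beta signalling; FGF and ERK response; WNT response; BMP response; heparan sulfate synthesis; Polycomb and DNA methylation; p53 response; integrated stress and unfolded protein response; hypoxia and glycolysis; cholesterol synthesis; cell cycle G2 and M; imprinted genes; genes variable among pluripotent clones; chromosome band 20q11.21; neighbours of ZNF263; mitochondrially encoded; replication-dependent histones; immediate early and heat shock. Some genes stand in more than one list, such as NODAL, LEFTY1, LEFTY2, GDF3 and TDGF1 in the core pluripotency and NODAL lists, FGF4 in the core and naive lists, and DUSP6 in the primed and FGF lists. The list of mitochondrially encoded genes holds protein-coding genes only, and none of them stands in the tables, so that list was not analysed here. The mitochondrial ribosomal RNAs stand in the tables as RNR1 and RNR2 and entered the tests of single genes. The tested genes of each of 23 chromosomes were tested in the same way.

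The comparisons, their tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except for some added later. Chosen after the data or a result were seen were leaving out both H1 libraries numbered 2, leaving out each library for the lists, the comparison with other lineages, the share of large changes that go the same way, the signs in H1 of genes called in H9 alone, and the count in the single libraries of genes changed at least 8-fold in H1. The rule names ZNF263; POU5F1, NANOG, SOX2, LIN28A and DNMT3B whatever their values; per cell line the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between knockout and wild-type libraries; the 2 called members of each list with the smallest adjusted p; the 6 rises and 6 falls with the largest smaller effect in both lines; the 4 highest and 4 lowest genes of 9-D against 9-1; the 3 largest differences between the lines per sign; and the 4 highest and 4 lowest ratios of each single library among genes with at least 50 counts. The limits of the threshold, of 1 CPM and of no overlap between the compared groups also hold for the genes of both lines and of 9-D against 9-1, and those of the threshold and 1 CPM for the differences between the lines. All picks by size of change leave out symbols of uncharacterised, antisense and small noncoding genes (LOC, LINC, MIR, SNOR, RNU, RP11- and -AS). Other genes named, namely members of counts of 5 or fewer, members that went against their list, TERF1 and TERT in H9, ISG15, and the genes in the plot of the single libraries, were chosen after their values were seen. Some genes that the rule picks or that lists count stayed in every test and count and are not reported here.

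The 3 single H1 libraries, of wild type, clone 1-5 and clone 1-10, have no replicates and were not tested. Log2 ratios to the single wild type used TMM-scaled CPM plus a pseudocount of 1, over genes with at least 10 counts. List medians were placed among 10000 random lists of equal size matched on mean expression in 20 bins. Overlaps of calls between H1 and H9 were compared with independent lists. Because the H9 clones share their wild type, 20 simulations of unchanged clones against those libraries were run.

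The comparisons were tested on simulated data, with negative binomial counts drawn from the real means and library sizes and 200 genes changed by known folds. For H1, with 14750 genes, 46% of 1.25-fold, 80% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes were recovered, with 7 false calls among 167. For H9, with 15201 genes, these shares were 52%, 84%, 94% and 100%, with 10 false calls among 175. For 9-D against 9-1, with 15216 genes, they were 52%, 82%, 96% and 100%, with 8 false calls among 173. For the difference between the lines, with 15622 genes, they were 22%, 76%, 88% and 100%, with 14 false calls among 157. Camera found both changed lists in each simulation and called 0 of 25 unchanged lists, with the preset and with the estimated correlation. These simulations drew each gene on its own, so they do not test the preset correlation where list members vary together. In the real H1 data the estimated correlation reached 0.498, for hypoxia and glycolysis genes. For the single libraries, a simulated list of 30 genes shifted by -0.5 fell at percentile 0 of the random lists and an unchanged list at percentile 93. Alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, a replicate block, a 2-fold minimum, a 3-group model for H9, an estimated correlation for lists, other pseudocounts and scalings for the single libraries, and leaving out each library in turn. No unused sample or file of counts remained.

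Reads of genes with near-identical copies or overlapping partners cannot be assigned with certainty in such counts. This applies to HSPA1A and HSPA1B, SERPINB4, LEFTY1 and LEFTY2, the exon-sharing PCDHGA10, the pseudogenes FAR2P1 and PDCL3P4, and KCNQ1OT1, which is antisense to KCNQ1 and whose strand the counting notes do not settle.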

Results

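Polyadenylated RNA was sequenced from H1 and H9, established lines of human embryonic stem cells, and from clones of each line edited at ZNF263, the gene of a zinc finger transcription factor. The question the submitters pose is what ZNF263 does in the control of pluripotency. The 18 libraries formed 8 groups. The replicated groups held 15 libraries, 3 each of H1 wild type, the homozygous H1 clone 1-10, H9 wild type and the homozygous H9 clones 9-1 and 9-D. The labels do not say whether the H1 and H9 libraries were made or sequenced together. A further H1 set held 1 library each of wild type, the heterozygous clone 1-5 and clone 1-10. Total counts were 12.3 to 15.3 M in H1 wild type, 9.66 to 17.7 M in clone 1-10, 14.2 to 16 M in H9 wild type, 13.6 to 21 M in clone 9-1 and 14.3 to 18 M in clone 9-D. The single libraries held 11.1 M (wild type), 13.2 M (1-5) and 13.4 M (1-10). A count of 0 allowed up to 3 counts, which was 0.143 CPM in the deepest and 0.310 CPM in the shallowest library. Levels below are TMM-scaled CPM with the SD between libraries.

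The targeted gene, ZNF263, was lower in each knockout library of the replicated groups than in any replicated wild-type library of its line, and most of its RNA remained. In H1, ZNF263 stood at 40.7 ± 1.22 CPM in wild type and 33.9 ± 1.98 CPM in clone 1-10 (n = 3 each). The log2 fold change was -0.27 (SE 0.076, adjusted p = 0.0156, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In H9, ZNF263 stood at 42.3 ± 2.27 CPM in wild type, 36.0 ± 1.49 CPM in clone 9-1 and 36.1 ± 1.42 CPM in clone 9-D (n = 3 each). The log2 fold change of both H9 clones together was -0.23 (SE 0.062, adjusted p = 0.0046, the same edgeR test with Benjamini-Hochberg adjustment). The single libraries held 39.3 CPM in wild type, 31.8 CPM in clone 1-5 and 33.3 CPM in clone 1-10. The labels do not say which part of ZNF263 was edited, so its RNA level does not show whether protein was lost. The H1 call was lost without wild-type replicate 2 (adjusted p = 0.0545) and without clone 1-10 replicate 1 (adjusted p = 0.0971, edgeR with Benjamini-Hochberg adjustment).

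**Figure D1:**
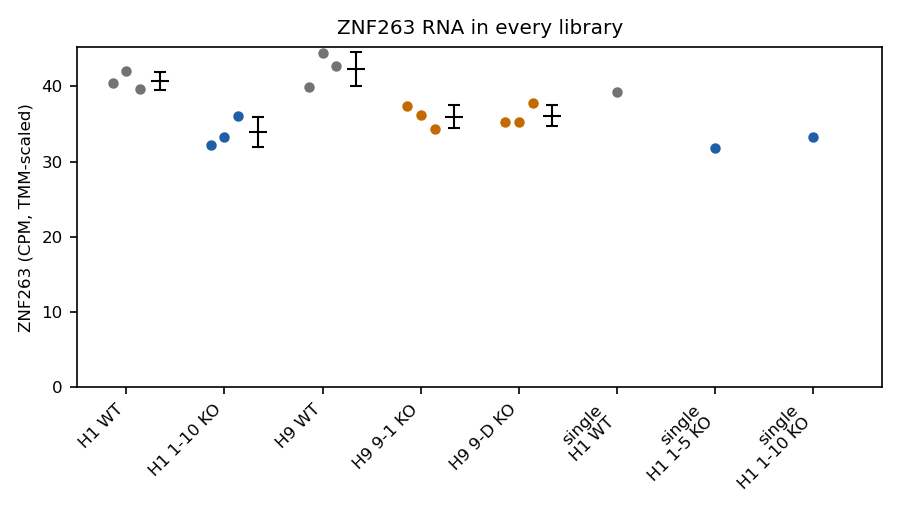
ZNF263 RNA per library in TMM-scaled CPM (vertical axis) for the 8 groups (horizontal axis); points are libraries, grey for wild type, blue for H1 and orange for H9 knockouts, and bars are the mean with its SD over 3 libraries. In H1 the knockout libraries lie at 33.9 ± 1.98 CPM against 40.7 ± 1.22 CPM in wild type.

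In H1, the comparison of clone 1-10 with wild type asked which genes differ between a clone with homozygous editing of ZNF263 and wild type. All 3 knockout libraries came from this clone, so the test measures the spread between its libraries and not between edited clones. Changes particular to the clone are therefore among the calls and cannot be told apart from those of the knockout. TMEM119, which encodes a transmembrane protein known from bone-forming cells and microglia, rose from 0.787 ± 0.307 to 6.31 ± 0.0351 CPM (n = 3 each). VGF, a neuropeptide precursor, rose from 15.8 ± 0.759 to 41.4 ± 3.01 CPM. PRTG, a cell surface protein of the early embryo, fell from 77.6 ± 7.74 to 21.3 ± 6.22 CPM. S100A6, a calcium-binding protein, fell from 5.78 ± 0.515 to 0.139 ± 0.103 CPM, and DLK1, an imprinted gene of the DLK1-MEG3 locus, fell from 24.1 ± 4.63 to 4.18 ± 1.30 CPM. The adjusted p of these 5 genes lay between 2.82e-14 for PRTG and 1.98e-10 for TMEM119 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Further large rises were those of AGBL4, a cytosolic carboxypeptidase, at a log2 fold change of 1.91 (SE 0.40), NR1I2, the pregnane X receptor, at 1.83 (SE 0.246), STMN4, a stathmin, at 1.59 (SE 0.416) and ATXN1 at 1.27 (SE 0.198). Several genes were close to silent in clone 1-10. ECHDC3 went from 527 counts over 3 wild-type libraries to 3 counts over 3 knockout libraries, a ratio of 183 with a counting interval of 62.3 to 891. TCEAL2 went from 87 counts to 0, at least 30.2-fold lower, and PKLR, the pyruvate kinase of liver and red cells, from 84 counts to 0, at least 29.2-fold lower, both against 3 counts over the group. GDA, guanine deaminase, fell from 5.19 ± 1.90 to 0.118 ± 0.0673 CPM and SEC14L4 from 5.59 ± 0.628 to 0.0828 ± 0.0977 CPM. Complement C3 fell from 2.02 ± 0.857 to 0.0828 ± 0.0977 CPM, and the pseudogene FAR2P1, whose reads near-identical copies can share, from 2.02 ± 0.643 to 0.0809 ± 0.0703 CPM. C11orf45 (log2 fold change 1.36) and SERPINB4 (1.16) passed as well, but neither did without wild-type replicate 2 (adjusted p = 0.05 and 0.171), wild-type replicate 3 (0.102 and 0.0502), clone 1-10 replicate 1 (0.0725 and 0.0841) or clone 1-10 replicate 2 (0.0814 and 0.0821, edgeR with Benjamini-Hochberg adjustment).

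Of 14897 genes tested in H1, 1827 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 747 higher and 1080 lower in clone 1-10. Among them 205 also changed at least 2-fold, 21 higher and 184 lower. DESeq2 called 1214 genes, 573 higher and 641 lower, and edgeR called 949 without wild-type replicate 3 and 1102 without clone 1-10 replicate 1. With a replicate block edgeR called 2926 genes, 1473 higher and 1453 lower, so the excess of lower genes depends on the model. The authors' deposited table for this comparison calls 1614 genes, 808 higher and 806 lower, and shares 1451 calls with the edgeR test.

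Pluripotency genes moved little in H1. Of 24 core pluripotency genes, 7 were higher and 0 lower in clone 1-10 (median log2 fold change 0.09), and 11 were higher and 1 lower when adjusted over the list alone. The list passed camera (adjusted p = 0.00123 with Benjamini-Hochberg adjustment; adjusted p = 0.137 with an estimated correlation). PRDM14, a transcription factor of pluripotent cells, rose from 87.8 ± 1.77 to 126 ± 2.09 CPM, and DNMT3B, a de novo DNA methyltransferase, from 2165 ± 85.6 to 2508 ± 86.0 CPM (n = 3 each). Log2 fold changes of the pluripotency factors NANOG (0.17, SE 0.062), POU5F1 (0.11, SE 0.044), SOX2 (0.07, SE 0.046) and LIN28A (0.06, SE 0.041) did not pass, with adjusted p between 0.077 and 0.348 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). NANOG passed without clone 1-10 replicate 2 (adjusted p = 0.0442), and POU5F1 passed with no filter on low counts (adjusted p = 0.0361, edgeR with Benjamini-Hochberg adjustment). With a replicate block, NANOG (adjusted p = 0.0186) and POU5F1 (adjusted p = 0.00334) both passed in edgeR with Benjamini-Hochberg adjustment. Without both libraries numbered 2, an alternative chosen after the data were seen, NANOG (adjusted p = 0.0218) and LIN28A (adjusted p = 0.0131) passed in edgeR with Benjamini-Hochberg adjustment.

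Primitive streak, neural and fibroblast genes were lower in clone 1-10 of H1, while the endoderm, mesoderm and neural crest lists did not pass (camera adjusted p = 0.965, 0.932 and 0.693 with Benjamini-Hochberg adjustment). The lists that did not pass had only 7, 5 and 7 tested members, with median log2 fold changes of -0.07, -0.14 and -0.55. They do not show that these lineages were spared, and the neural crest median was close to that of the streak genes. Of 11 primitive streak and mesendoderm genes tested, 5 fell (T, MIXL1, EOMES, FGF17 and SP5) and 0 rose, as when adjusted over the list alone (median log2 fold change -0.59; camera adjusted p = 6.61e-09 with Benjamini-Hochberg adjustment, and adjusted p = 0.137 with an estimated correlation). EOMES, a T-box factor of mesendoderm, fell from 7.34 ± 0.463 to 1.89 ± 0.955 CPM, and MIXL1, a homeobox gene of the primitive streak, from 9.13 ± 0.300 to 3.04 ± 1.79 CPM (n = 3 each). Of 21 neuroectoderm and neuron genes, 11 fell and 0 rose, 14 and 0 when adjusted over the list alone (median -0.85; camera adjusted p = 7.88e-12, and adjusted p = 0.137 with an estimated correlation). SIX3, a homeobox gene of the forebrain, fell from 7.51 ± 0.741 to 1.23 ± 0.392 CPM, and RAX, a homeobox gene of the eye field, from 4.10 ± 0.446 to 0.593 ± 0.0320 CPM. Of 12 fibroblast and feeder genes, 5 fell (COL1A2, COL3A1, COL5A1, S100A4 and VIM) and 0 rose, 6 and 0 when adjusted over the list alone (median -0.28; camera adjusted p = 0.000534, and adjusted p = 0.319 with an estimated correlation). COL3A1 fell from 4.13 ± 0.664 to 1.23 ± 0.739 CPM. COL1A2 had a log2 fold change of -0.28 and lost its call without wild-type replicate 3 (adjusted p = 0.0597, edgeR with Benjamini-Hochberg adjustment). In the separate single libraries, median log2 ratios of clone 1-10 to wild type were 0.29 for 7 streak, -0.10 for 19 neural and -0.16 for 11 fibroblast genes. Against matched random lists, the streak median lay above, the neural median inside and the fibroblast median below. The fall of the streak genes was thus not seen there, with 1 library per group. The median of 7 neural crest genes there was -0.283, below its random lists (-0.235 to 0.161).

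Signalling targets and stress genes of H1 moved in both directions. Of 20 FGF and ERK response genes, 6 fell and 0 rose, 8 and 0 when adjusted over the list alone (median log2 fold change -0.11; camera adjusted p = 0.00123, and adjusted p = 0.137 with an estimated correlation). DUSP6, a phosphatase that restrains ERK, fell from 233 ± 3.70 to 172 ± 11.5 CPM, and SPRY1, a feedback inhibitor of the pathway, from 35.6 ± 0.127 to 25.9 ± 1.87 CPM (n = 3 each). Of 19 WNT response genes, 4 fell (SP5, NKD1, DKK1 and APCDD1) and 1 rose (FZD5), 8 and 2 when adjusted over the list alone (median -0.37; camera adjusted p = 0.00745, 0.0586 without wild-type replicate 2, and adjusted p = 0.26 with an estimated correlation). SP5, a WNT target, changed by -2.17 (SE 0.281) and NKD1, a WNT antagonist, by -0.54 (SE 0.135) on the log2 scale, NKD1 without a call when wild-type replicate 2 was left out (adjusted p = 0.0512, edgeR with Benjamini-Hochberg adjustment). Of 32 genes of heparan sulfate synthesis, 7 fell and 1 rose (GPC4), 10 and 1 when adjusted over the list alone (median -0.10; camera adjusted p = 0.0177, 0.0677 without clone 1-10 replicate 3, and adjusted p = 0.319 with an estimated correlation). SULF1, which removes sulfate from heparan sulfate, fell from 14.7 ± 1.14 to 7.33 ± 0.965 CPM, and HS6ST2, a sulfotransferase, from 12.5 ± 1.15 to 7.49 ± 0.644 CPM. Of 22 hypoxia and glycolysis genes, 7 fell and 0 rose, 10 and 0 when adjusted over the list alone (median -0.15; camera adjusted p = 6.55e-08, and adjusted p = 0.319 with an estimated correlation). BNIP3, a hypoxia-induced gene of mitophagy, fell from 62.5 ± 24.8 to 21.7 ± 1.02 CPM, and SLC2A1, a glucose transporter, from 431 ± 45.5 to 294 ± 18.8 CPM. Of 22 genes of the integrated stress and unfolded protein response, 5 rose (ASNS, CHAC1, SLC7A11, HSPA5 and MANF) and 1 fell (DDIT4), 9 and 1 when adjusted over the list alone (median 0.13; camera adjusted p = 0.0215, 0.139 without wild-type replicate 1, 0.0833 without wild-type replicate 3, and adjusted p = 0.319 with an estimated correlation). HSPA5, an endoplasmic reticulum chaperone, rose from 856 ± 15.7 to 1023 ± 7.51 CPM, while DDIT4, an inhibitor of mTORC1 induced by stress, fell from 80.6 ± 28.3 to 27.8 ± 1.48 CPM. Of 15 immediate early and heat shock genes, 5 rose (JUN, HSPA1A, HSPA1B, HSPH1 and HSPA8) and 0 fell, as when adjusted over the list alone (median 0.09; camera adjusted p = 0.00204, and adjusted p = 0.137 with an estimated correlation). JUN rose from 22.1 ± 1.97 to 36.8 ± 5.03 CPM and the chaperone HSPA8 from 2151 ± 82.6 to 2823 ± 46.3 CPM. The other 16 of 26 lists tested in H1 did not pass.

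In H9, clones 9-1 and 9-D together were compared with wild type to ask the same question in another line. GDA rose from 0.195 ± 0.0597 CPM (n = 3) to 19.1 ± 3.5 CPM (n = 6), and DPEP3, a membrane dipeptidase, from 1.37 ± 0.57 to 15.2 ± 4.22 CPM. The zinc finger gene ZNF585B rose from 0.388 ± 0.0922 to 5.96 ± 1.11 CPM. GRIN2A, an NMDA receptor subunit, fell from 52.7 ± 23.8 to 6.69 ± 0.938 CPM. S100A6 fell from 4.68 ± 0.465 to 0.481 ± 0.287 CPM, and ZNF132 from 3.76 ± 0.348 to 0.559 ± 0.168 CPM. The adjusted p of these 6 genes lay between 2.19e-18 for GDA and 1.65e-10 for ZNF132 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Other large rises on the log2 scale were CYP4F22 at 3.67 (SE 0.62), ZNF528 at 3.67 (SE 0.553), the chemokine PF4 at 3.46 (SE 0.498), CCDC169 at 3.41 (SE 0.298) and RGN, regucalcin, at 3.23 (SE 0.336). ZNF667 went from 385 counts over 3 wild-type libraries to 1 count over 6 knockout libraries, a ratio of 835 with a counting interval of 149 to 33000. PUS7L, a pseudouridine synthase homologue, went from 293 counts to 2 (ratio 318, interval 87.1 to 2630), and IRAK4, a kinase of Toll-like receptor signalling, from 136 counts to 1 (ratio 295, interval 52.0 to 11700). PUS7L and IRAK4 are adjacent genes in the RefSeq annotation. TMEM88 fell from 3.5 ± 1.04 to 0.722 ± 0.15 CPM. PCDHGA10, whose reads other protocadherins of its cluster can share, fell from 15.2 ± 0.889 to 1.42 ± 0.186 CPM.

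Of 15411 genes tested in H9, 4574 passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 2213 higher and 2361 lower in the knockout clones. Among them 456 also changed at least 2-fold, 227 higher and 229 lower. The authors' deposited table for H9 calls 4255 genes, 2207 higher and 2048 lower, and shares 4117 calls with the edgeR test.

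Pluripotency genes were mostly higher in the H9 knockouts. Of 24 core pluripotency genes, 20 rose and 2 fell (TERF1 and TERT), as when adjusted over the list alone (median log2 fold change 0.37; camera adjusted p = 9.64e-15 with Benjamini-Hochberg adjustment, and adjusted p = 0.0142 with an estimated correlation). GAL, the neuropeptide galanin, rose from 67.5 ± 4.50 CPM (n = 3) to 160 ± 13.8 CPM (n = 6), ZFP42, also called REX1, from 122 ± 5.38 to 226 ± 8.53 CPM, DNMT3B from 1527 ± 118 to 2032 ± 48.5 CPM and NANOG from 44.9 ± 2.42 to 60.4 ± 3.18 CPM. SOX2 had a log2 fold change of 0.05 (SE 0.047, adjusted p = 0.502, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). POU5F1, at 0.13 (SE 0.050, adjusted p = 0.0403), lost its call without wild-type replicate 1 (0.153) or 3 (0.19), clone 9-1 replicate 3 (0.0899), clone 9-D replicate 2 (0.0547) or clone 9-D replicate 3 (0.0606, edgeR with Benjamini-Hochberg adjustment). LIN28A, at 0.12 (SE 0.046, adjusted p = 0.0474), kept its call only without clone 9-D replicate 3; leaving out any other library gave adjusted p between 0.0568 and 0.153 (edgeR with Benjamini-Hochberg adjustment). Of 11 naive pluripotency genes, 8 rose and 1 fell (SUSD2), 10 and 1 when adjusted over the list alone (median 0.80; camera adjusted p = 2.94e-06, and adjusted p = 0.0142 with an estimated correlation). For each clone against wild type with an estimated correlation, both lists passed in 9-D (camera adjusted p = 0.0278 each with Benjamini-Hochberg adjustment) and neither did in 9-1 (0.159 for core and 0.0552 for naive genes). The medians were close, at 0.39 in 9-1 and 0.37 in 9-D for core genes and 0.84 and 0.76 for naive genes. With the preset correlation, camera called both lists in both clones. TFAP2C, a transcription factor of naive cells and germ cells, rose from 5.66 ± 0.657 to 14.5 ± 2.09 CPM. TFCP2, also counted in the naive list, rose from 33.6 ± 3.51 to 58.4 ± 3.97 CPM. TFCP2 is a broadly expressed paralogue of TFCP2L1 and not itself a marker of naive cells. Of 17 primed pluripotency genes, 8 fell and 4 rose (FGF2, SALL2, FZD7 and USP44), as when adjusted over the list alone (median -0.10; camera adjusted p = 0.0166, and adjusted p = 0.284 with an estimated correlation). DUSP6 fell from 133 ± 8.04 to 63.0 ± 2.99 CPM, while FGF2, a growth factor that sustains primed cells, rose from 209 ± 2.57 to 296 ± 20.8 CPM.

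Signalling, stress and sterol genes of H9 changed as well. Of 22 NODAL and TGF-beta signalling genes, 7 rose and 3 fell, among them ACVR1B and TGFBR1, 8 and 3 when adjusted over the list alone (median log2 fold change 0.09; camera adjusted p = 0.0284, 0.0787 without wild-type replicate 1, and adjusted p = 0.345 with an estimated correlation). NODAL, LEFTY1, LEFTY2, GDF3 and TDGF1 also stand in the core pluripotency list, where 20 of 24 genes rose. The result of the NODAL list is thus not separate from that of the core list. SKIL, a repressor of SMAD signalling, rose from 147 ± 8.43 CPM (n = 3) to 237 ± 21.5 CPM (n = 6), and ACVR1B, a receptor for NODAL and activin, fell from 56.1 ± 1.13 to 36.2 ± 1.64 CPM. Of 17 WNT response genes, 7 fell and 2 rose (AXIN2 and FZD5), as when adjusted over the list alone (median -0.28; camera adjusted p = 0.00549, and adjusted p = 0.284 with an estimated correlation). SFRP1, a secreted WNT antagonist, fell from 1429 ± 10.2 to 724 ± 68.0 CPM, and the WNT receptor FZD8 from 27.3 ± 2.13 to 16 ± 0.970 CPM. Of 32 genes of heparan sulfate synthesis, 12 fell and 4 rose (HS3ST1, HS3ST2, HS3ST5 and SULF2), 13 and 5 when adjusted over the list alone (median -0.10; camera adjusted p = 0.0149, and adjusted p = 0.284 with an estimated correlation). B3GAT3, which completes the linker of heparan sulfate chains, fell from 38.6 ± 3.82 to 24.7 ± 2.22 CPM, and the glypican GPC6 from 56.1 ± 3.20 to 38.9 ± 2.39 CPM. Of 22 genes of the integrated stress and unfolded protein response, 19 rose and 0 fell, 20 and 0 when adjusted over the list alone (median 0.23; camera adjusted p = 8.94e-08, and adjusted p = 0.144 with an estimated correlation). CHAC1, which degrades glutathione, rose from 24.8 ± 2.82 to 38.2 ± 2.30 CPM, and PSAT1, an enzyme of serine synthesis, from 318 ± 10.3 to 406 ± 14.4 CPM. Of 24 cholesterol synthesis genes, 8 rose and 1 fell (SREBF2), as when adjusted over the list alone (median 0.06; camera adjusted p = 0.0161, 0.0787 without wild-type replicate 1, and adjusted p = 0.343 with an estimated correlation). MVD, an enzyme of the mevalonate pathway, rose from 87.4 ± 3.72 to 111 ± 7.18 CPM. The other 19 of 27 lists tested in H9 did not pass.

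**Figure D2:**
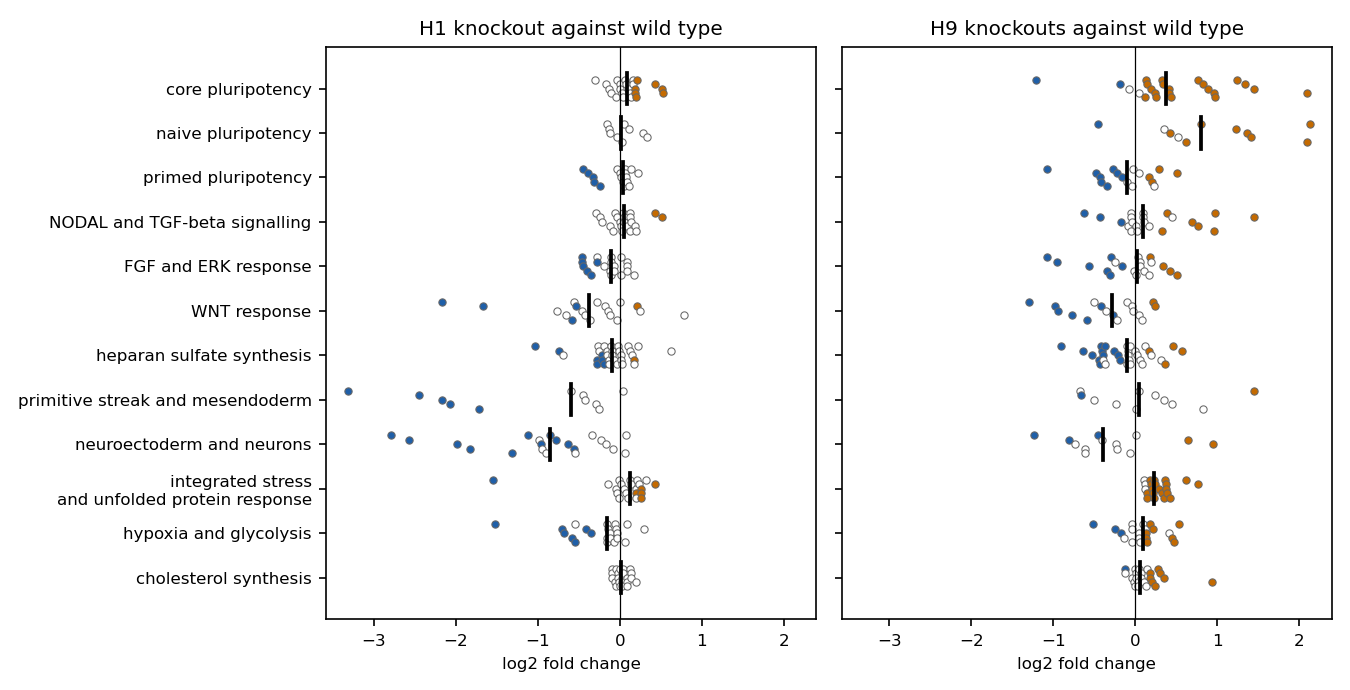
Log2 fold change (horizontal axis) of each tested member of 12 gene lists (vertical axis) in H1 (left) and H9 (right); filled points passed the test, orange higher and blue lower in the knockouts, white points did not pass, and black bars are medians. The median of the neuroectoderm and neuron list lies at -0.85 in H1, and that of the core pluripotency list at 0.09 in H1 and 0.37 in H9.

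The H1 and H9 comparisons share no library, so genes called in both were counted. TMEM119 rose to a like extent in both lines, by 2.99 (SE 0.252) in H1 and 3.11 (SE 0.300) in H9 on the log2 scale. VGF rose by 1.40 and 1.14, AGBL4 by 1.91 and 3.02, and STMN4 by 1.59 and 1.94. Falls in both lines included S100A6, with log2 fold changes of -5.27 in H1 and -3.22 in H9, PRTG (-1.92 and -1.43), GRM3, a metabotropic glutamate receptor (-1.50 and -1.40), and RAI1 (-1.38 and -1.87). ADAMTS9, a secreted metalloproteinase (-1.31 and -1.82), and TSGA10IP (-1.51 and -1.51) completed the 6 falls. Among the 6 rises, SERPINB4 (1.16 and 2.36) lost its H1 call without single libraries, as given above, and LRRTM1 (0.93 and 1.19) lost it without clone 1-10 replicate 1 (adjusted p = 0.0731) and in DESeq2 (adjusted p = 0.0746, both with Benjamini-Hochberg adjustment against edgeR's 0.014). Over 14627 genes tested in both lines, 370 rose in both, where independent lists give 107.8, and 536 fell in both, where independent lists give 164.3. Another 101 genes passed in both lines with opposite signs, so that 90% of 1007 shared calls went the same way (exact 95% interval 87.9 to 91.8%). These 1007 genes were among 1785 called in H1 and 4428 called in H9. Across all genes tested in both lines, the correlation of the log2 fold changes was 0.309. The 906 genes became 520 without H1 wild-type replicate 3 and 569 without clone 1-10 replicate 1.

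**Figure D3:**
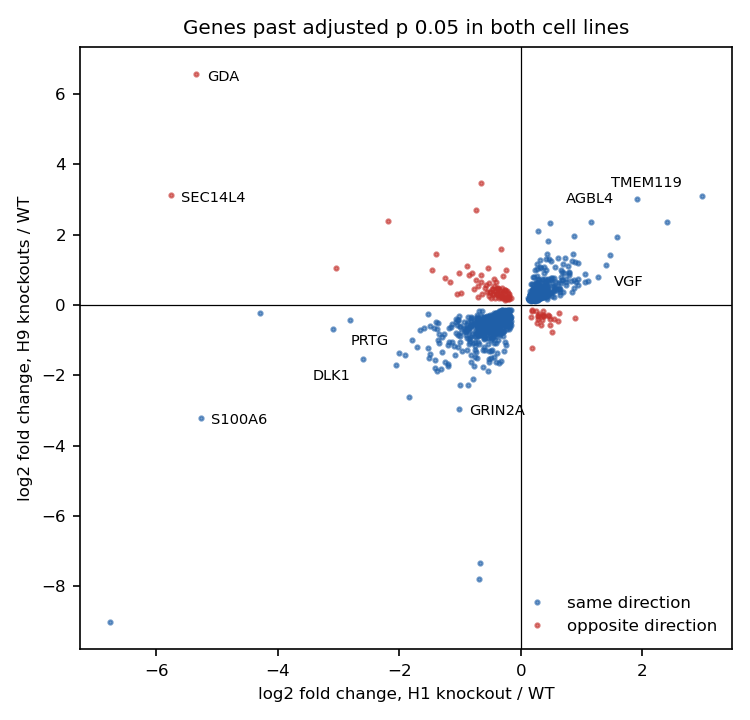
Log2 fold change of knockout over wild type in H1 (horizontal axis) and H9 (vertical axis) of the 1007 genes past the threshold in both lines; each point is a gene, blue for the same and red for opposite directions. The 906 blue genes lie in the lower left and upper right quadrants, and the 3 points below -6 in H9 rest on counts near 0.

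**Figure D4:**
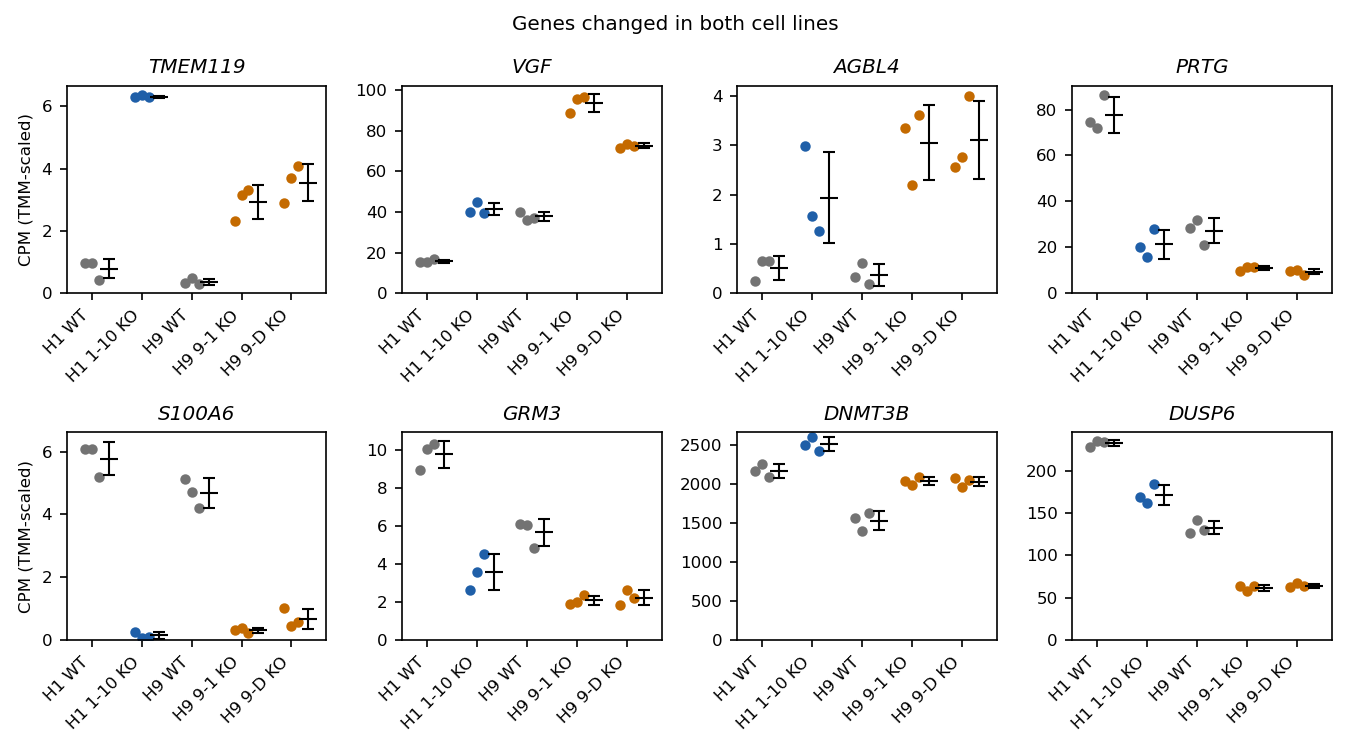
Level per library in TMM-scaled CPM (vertical axes) of 8 genes called in both lines, by group (horizontal axes); points are libraries, grey for wild type, blue for H1 and orange for H9 knockouts, and bars are the mean with its SD over 3 libraries, scaled within each line. TMEM119 rises from 0.787 to 6.31 CPM in H1 and from 0.373 to 3.24 CPM over the 6 H9 knockout libraries.

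The H9 clones were also compared singly, to see how far they share their changes and differ. Clone 9-1 differed from wild type in 4053 genes (1965 higher, 2088 lower) and clone 9-D in 3619 (1770 higher, 1849 lower). Of these, 1380 rose and 1469 fell in both clones, and 0 went opposite ways. Independent lists give 225.7 and 250.5. The clones share their 3 wild-type libraries, too few to split between them, so the sharing was set against simulations. Across genes, which are not independent replicates, the covariance of the log2 fold changes was 0.184, against a median of 0.0136 in 20 simulations of unchanged clones, a difference of 0.170. The correlation was 0.898 against a median of 0.51 in these simulations, which drew each gene on its own. The direct comparison of 9-D with 9-1 called 47 of 15411 genes, 25 higher and 22 lower in 9-D. TERF1, a telomere-binding protein, was at 521 ± 35.7 CPM in wild type, 93.5 ± 3.83 CPM in 9-1 and 356 ± 16 CPM in 9-D (n = 3 each). MAGI2, a scaffold protein, was at 24.0 ± 1.28, 13.4 ± 0.552 and 25.4 ± 2.07 CPM. SBSPON was at 8.22 ± 0.864, 2.81 ± 0.653 and 6.07 ± 0.110 CPM, and NKAIN2 at 0.684 ± 0.301, 3.29 ± 1.38 and 0.528 ± 0.173 CPM. Between the clones, the log2 fold changes of TERF1 (1.93), MAGI2 (0.93), SBSPON (1.12) and NKAIN2 (-2.61) had adjusted p between 2.03e-23 for TERF1 and 0.000353 for SBSPON (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The count was 28 without clone 9-1 replicate 1, 27 without its replicate 2, 28 without its replicate 3, 25 without clone 9-D replicate 2 and 29 without its replicate 3.

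Whether the knockout effect differed between H9 and H1 was tested as the difference of the log2 fold changes, H9 minus H1. GDA and SEC14L4 moved in opposite directions. GDA fell in H1 and rose in H9, a difference of 11.90 (SE 0.522). SEC14L4 fell in H1 and rose in H9 from 0.329 ± 0.0844 CPM (n = 3) to 2.89 ± 0.358 CPM (n = 6), a difference of 8.88 (SE 0.497). Both genes held a mean under 0.310 CPM in clone 1-10, and GDA in H9 wild type as well, so the size of these differences is uncertain. PUS7L fell to near 0 in H9, while in H1 its log2 fold change was -0.70 (SE 0.122) from 18.4 ± 1.62 CPM in wild type (n = 3), and its neighbour IRAK4 fell in H1 from 4.43 ± 0.820 to 2.81 ± 0.223 CPM. TCEAL2, at 0 counts in clone 1-10, stood at 18.7 ± 2.62 CPM in H9 wild type and 16.4 ± 2.15 CPM in the H9 knockouts. MOG, a myelin protein, was too low for the test in H1 and fell in H9 from 3.46 ± 1.22 to 0.720 ± 0.238 CPM. Its fitted difference rests in part on 5 counts in H1 wild type and 20 in clone 1-10. The adjusted p of these differences lay between 1.35e-19 for GDA and 0.00011 for MOG (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 15802 genes tested, 1380 differed between the lines, 784 with the higher and 596 with the lower effect in H9. H1 entered this test with clone 1-10 alone, and the spread in H1 is that between its libraries. A change particular to that clone is therefore counted as a difference between the lines. The effect on ZNF263 itself did not differ detectably (0.04, SE 0.093, adjusted p = 0.873, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Core pluripotency genes had the higher effect in H9 for 8 members and the lower for 1, TERF1 (camera adjusted p = 1.97e-08, and adjusted p = 0.0233 with an estimated correlation). In the naive list, 5 members, TFCP2 among them, had the higher and 0 the lower effect (camera adjusted p = 0.000376, and adjusted p = 0.0233 with an estimated correlation). The effect on primitive streak and mesendoderm genes was higher in H9 for 5 members (T, MIXL1, EOMES, FGF8 and FGF17) and lower for 0 (camera adjusted p = 0.00575, and adjusted p = 0.44 with an estimated correlation). For hypoxia and glycolysis genes it was higher for 11 and lower for 0 (camera adjusted p = 2.56e-09, and adjusted p = 0.111 with an estimated correlation).

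The 3 single H1 libraries compare the heterozygous clone 1-5 and the homozygous clone 1-10 with wild type, without replicates, and carry no test. Genes that rose in the replicated H1 comparison (743 with enough counts) had a median log2 ratio to wild type of 0.10 in 1-10 and 0.10 in 1-5, above the central 95% of matched random lists (0.02 to 0.03 and 0.00 to 0.03). Genes that fell there (1047) had medians of -0.16 in 1-10 and -0.12 in 1-5, below the random lists (-0.02 to 0.01 in both). Both ratios share the single wild-type library, so a peculiarity of that library would move 1-5 and 1-10 alike. The random lists measure the sampling of genes and not the variation between libraries. TMEM119 had 11 counts in wild type, 60 in 1-5 and 87 in 1-10. The co-chaperone DNAJA4 had 77, 113 and 213 counts, ENPP2, which makes lysophosphatidic acid, 39, 76 and 104, and ANGPT1, a ligand of endothelial receptors, 48, 74 and 119. The interferon-induced genes IFIT1 (429, 1864 and 19 counts), IFIT2 (286, 1067 and 3) and IFIT3 (118, 541 and 5) were higher in 1-5 and lower in 1-10. Neuronal pentraxin NPTX1 had 417, 219 and 137 counts, and TAF9B, a subunit of the TFIID complex, 76, 14 and 11. MPPED2 had 75, 37 and 55 counts and DPEP3 80, 40 and 81. The RNA components of RNase MRP and RNase P, RMRP (1, 66 and 2) and RPPH1 (9, 81 and 7), were higher in 1-5, though such RNAs lack poly(A) tails. In a count chosen after the data were seen, of 11 genes that changed at least 8-fold in the replicated H1 comparison and had at least 20 counts in the single wild-type or 1-10 library, 8 lay within 2-fold of wild type in 1-5 and 1 (SLC16A3) did in 1-10. ECHDC3 had 135 counts in wild type, 175 in 1-5 and 0 in 1-10, S100A6 49, 61 and 0, and PKLR 28, 47 and 0. FAR2P1, TAF9B and ZNF280D were more than 2-fold lower in both clones. The authors' deposited tables for the single libraries call 0 genes in either clone (lowest adjusted p 0.999, DESeq2), with ZNF263 at -0.24 in 1-10 and -0.31 in 1-5 on the log2 scale.

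**Figure D5:**
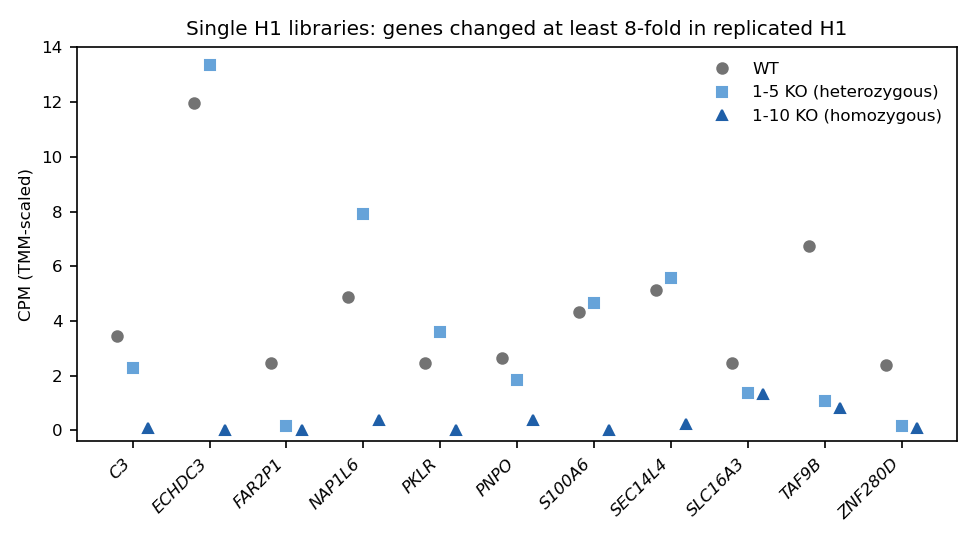
Level in TMM-scaled CPM (vertical axis) of the 11 genes (horizontal axis) changed at least 8-fold in the replicated H1 comparison, in the single libraries of wild type (circles), clone 1-5 (squares) and clone 1-10 (triangles), 1 library each. In clone 1-5, 8 of the 11 genes lie within 2-fold of wild type, and in clone 1-10 1 does.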

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

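In this part, the comparison with other lineages and the share of large changes that go the same way were tests chosen only after the result was seen.

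Several genes responded in opposite ways or to different extents in H9 and H1, and the difference itself was tested for each. H1 was represented by clone 1-10 alone, so changes particular to that clone are not set apart. Differences of the log2 fold change, H9 minus H1, are given below for genes picked by the rule, with adjusted p between 1.35e-19 for GDA and 0.0371 for TMEM88 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among genes picked for the size of a change, higher effects in H9 were those of GDA (11.90), SEC14L4 (8.88), TCEAL2 (7.81), PKLR (7.03), ECHDC3 (5.84), C3 (4.37), DPEP3 (4.11), FAR2P1 (4.07), ZNF585B (3.77), CCDC169 (3.66), RGN (3.20), PF4 (3.19), ZNF528 (2.95) and S100A6 (2.06). Lower effects in H9 among them were those of PUS7L (-7.08), IRAK4 (-6.64), MOG (-4.14), PCDHGA10 (-3.48), ZNF132 (-2.57), GRIN2A (-1.94) and TMEM88 (-1.28). The fitted values of 14 genes rest on a group with a mean under 0.310 CPM, are uncertain in size and are no bounds. That group was clone 1-10 for GDA, SEC14L4, TCEAL2, PKLR, ECHDC3, C3, FAR2P1 and S100A6, H1 wild type for MOG, H9 wild type for GDA, PKLR, ECHDC3, RGN, PF4 and ZNF528, and the H9 knockouts for PKLR, ECHDC3, IRAK4 and PUS7L. PKLR and ECHDC3 were too low for the test in H9, and PF4 and MOG in H1. Among members of the pluripotency lists the differences were GAL 1.09, ZFP42 1.00, NODAL 1.03, TFAP2C 1.08, TFCP2 0.75, FGF2 0.42, DUSP6 -0.64 and CDH2 0.28. Among lineage genes they were EOMES 2.40, MIXL1 1.94, FGF8 1.70, FOXA2 1.88, TUBB3 0.58, NCAM1 -1.01 and COL1A1 0.88. Among signalling and heparan sulfate genes they were SPRY1 0.62, EGR1 -1.14, SKIL 0.55, ACVR1B -0.54, SFRP1 -0.99, FZD8 -1.02, SULF1 0.60 and GPC6 -0.44. Stress, hypoxia, sterol and cell cycle genes gave DDIT4 1.66, CHAC1 0.37, PSAT1 0.25, SESN2 0.42, AEN 0.34, CDKN1A 0.92, BNIP3 1.28, SLC2A1 0.50, PFKP 0.59, MVD 0.44 and PLK1 0.48. Other list members gave KDM2B 0.36, TET1 0.37, CSMD1 1.85, ZNF354C 0.88 and CCM2L -0.80.

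Gene lists also differed between the lines, each with a higher effect in H9. By camera with Benjamini-Hochberg adjustment, the adjusted p was 1.97e-08 for core and 0.000376 for naive pluripotency (adjusted p = 0.0233 with an estimated correlation for each). It was 0.00575 for primitive streak and mesendoderm (adjusted p = 0.44 with an estimated correlation) and 2.56e-09 for hypoxia and glycolysis (adjusted p = 0.111 with an estimated correlation), by camera, and the counts of these 4 lists stand in the report. Further lists were the p53 response (5 higher, 0 lower; adjusted p = 0.00518, and adjusted p = 0.0945 with an estimated correlation) and the integrated stress and unfolded protein response (6 and 0; adjusted p = 0.000383, and adjusted p = 0.119 with an estimated correlation). Genes variable among pluripotent clones had 3 members higher (FAM19A5, CSMD1 and ZNF354C) and 0 lower (adjusted p = 0.0118, and adjusted p = 0.0945 with an estimated correlation, by camera). Cholesterol synthesis had 4 higher, among them MVD, LSS and TM7SF2, and 0 lower (adjusted p = 0.0389, and adjusted p = 0.44 with an estimated correlation). It was lost without H1 wild-type replicate 2 (0.063), clone 1-10 replicate 3 (0.0709), H9 wild-type replicate 1 (0.22), clone 9-1 replicate 2 (0.0628) or 3 (0.0683), or clone 9-D replicate 1 (0.101, camera). Definitive endoderm had 2 higher (FOXA2 and GATA6) and 0 lower (adjusted p = 0.0389, and adjusted p = 0.3 with an estimated correlation). It was lost without H1 wild-type replicate 1 (0.0849), clone 1-10 replicate 1 (0.0974) or 2 (0.119), H9 wild-type replicate 2 (0.0725) or 3 (0.06), clone 9-1 replicate 3 (0.0693) or clone 9-D replicate 1 (0.0572, camera).

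Among 81 genes picked by the rule in H9, 5 had a library far from the other 5 of the 6 knockout libraries, and chance does this in about 1 of 20 genes. On a log2 scale of CPM with a prior count of 1, the gap to the nearest library over the whole range was 1 for IRAK4 and 1 for ZNF667, each with 1 count in a single library, 0.76 for CCM2L (5.32 CPM in clone 9-D replicate 2, others 3.04 to 3.48), 0.775 for AFP (2.55 CPM in clone 9-D replicate 2, others 4.33 to 5.04) and 0.626 for DLK1 (3.69 CPM in clone 9-1 replicate 3, others 1.03 to 1.67).

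Neural and primitive streak genes, such as RAX, SIX3, EOMES and MIXL1, were lower in clone 1-10 of H1, with a median log2 fold change of -0.81 over 32 members. The endoderm, mesoderm, trophoblast and fibroblast lists had a median of -0.23 over 28 other genes, of which 8 were called lower and 1 higher. The difference of 0.59 (permutation p = 0.00095) decides nothing, since the neural and streak lists were set apart because they had fallen, so fewer differentiated cells of every lineage stay a possible explanation. In the single H1 libraries the list medians of clone 1-10 had opposite signs. They were 0.29 for 7 streak genes (above the random lists, -0.37 to 0.22) and -0.10 for 19 neural genes (inside -0.18 to 0.10). The 26 together had a median of -0.006, inside its random lists (-0.17 to 0.08). That is the outcome written beforehand for the state of the wild-type cultures. It was set aside after the separate lists were seen, since it averages over medians of opposite sign. Only the streak median lay outside its random lists, so an opposite change of the neural genes was not shown. With 1 library per group, the state of the wild-type cultures in the replicated H1 comparison and an effect of the knockout cannot be told apart.

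GDA and SEC14L4 changed at least 8-fold and in opposite directions in H1 and H9. Of 12 genes called in both lines and changed at least 8-fold in either, 8 went the same way, or 66.7% (exact 95% interval 34.9 to 90.1%), against 90.3% of 995 genes with smaller changes. At a limit of 4-fold, 21 of 27 went the same way, or 77.8% (interval 57.7 to 91.4%), against 90.3% of 980. A limit of 2-fold gave no lower share, with 136 of 152, or 89.5% (interval 83.5 to 93.9%), against 90.1% of 855. Variation between clones that is not the knockout could lower the share for large changes, and an effect of the knockout that depends on the line could as well. The share decides between neither, so these cannot be told apart.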

How the results depend on the processing

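Leaving out both H1 libraries numbered 2, and each library for the gene lists, were alternatives chosen only after the data were seen. The H1 count of 1827 genes became 1214 with DESeq2, 2926 with a replicate block (1473 higher and 1453 lower, against 747 and 1080), 205 with a 2-fold minimum, 2477 without both libraries numbered 2 (1524 shared) and 949 to 2100 leaving out a library. The H9 count of 4574 became 456 with a 2-fold minimum and stayed between 3486 and 4903 leaving out a library. Leaving out a library, the 47 genes between clones 9-D and 9-1 became 25 to 53, and the 906 genes called alike in both lines 520 to 990. With no filter on low counts they became 64 and 1009. The 906 became 1348 with the block and 1086 without both H1 libraries numbered 2. Whether library numbers pair the samples is not settled by the residual correlations. In H1, those of knockout with wild-type libraries were 0.086 to 0.343 at the same number and -0.286 to 0.128 otherwise. In H9 they were -0.109 to 0.198 and -0.194 to 0.184. Between the H9 clones they were 0.007 to 0.22 at the same number and -0.281 to 0.139 otherwise. Not every library correlated best with its own number, as clone 1-10 replicate 3 did so with wild-type replicate 1 (0.128 against 0.086). With the block, NANOG (adjusted p = 0.0186) and POU5F1 (adjusted p = 0.00334, edgeR with Benjamini-Hochberg adjustment) passed in H1, and the endoderm list of the difference between the lines did not (camera adjusted p = 0.0554). With an estimated correlation, camera called 0 lists in H1, 2 in H9 and 2 for the difference between the lines, in place of 10, 8 and 9. ZNF263 in H1 ranged from -0.31 to -0.24 on the log2 scale leaving out a library, with adjusted p = 0.0545 without wild-type replicate 2 and 0.0971 without clone 1-10 replicate 1 (edgeR with Benjamini-Hochberg adjustment). In the single libraries, scaling by library total gave medians of 0.071 (1-10) and 0.07 (1-5) over the genes higher in H1, and -0.19 (1-10) and -0.15 (1-5) over the lower ones, where a pseudocount of 0.1 gave -0.18 in 1-10. No gene picked by the rule and no list that passed reversed its direction in the settings fitted for it. The larger side of the counts did change, in H1 with the block as above, in H9 from 2361 lower and 2213 higher to 2207 higher and 2050 lower with DESeq2, 2408 and 2327 with no filter, and 2500 and 2403 without clone 9-D replicate 3. In 9-D against 9-1, 25 higher and 22 lower became 12 and 16 without replicate 1 or 3 of clone 9-1. The single clones against wild type changed in the same way in DESeq2 and with no filter. Clone 9-D also did so with the block (1966 higher and 1952 lower), without any of its own replicates, and without 9-1 replicate 1 or 3. Clone 9-1 did so without 9-D replicate 3 (2190 higher and 2181 lower). Over the genes picked by the rule, leaving out a library ended the call in 47 of 402 H1 values, in 17 of 67 genes, and made 1; it ended 15 of 729 in H9, in 4 of 81 genes, and 18 of 72 between the clones, in 4 of 8 genes. DESeq2 ended the call of 9 of 64 genes in H1, 0 of 81 in H9 and 2 of 8 between the clones. A further 55 differences between the lines were not refitted. Fewer libraries weaken a test by construction, though some counts rose; the cause of the other changes was not tested. At the shallowest depth, genes under 0.310 CPM cannot be told from 0.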

Other observations

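In this part, the signs in H1 of the genes called in H9 alone were a test chosen only after the result was seen.

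Gene lists that did not pass still held called genes. In H9, the endoderm factor FOXA2 rose from 0.455 to 1.66 CPM and AFP from 1.98 to 4.24 CPM, and PDGFRA, a receptor of mesoderm, from 4.20 to 9.34 CPM, while the adhesion molecule NCAM1 fell from 21.3 to 9.01 CPM (n = 3 and 6). By camera with Benjamini-Hochberg adjustment, with called members higher and lower, the H9 lists gave definitive endoderm 4 and 0 (adjusted p = 0.0709), mesoderm 4 and 1 (0.108), neuroectoderm and neurons 2 and 3 (0.0806), neural crest 3 and 1 (0.161), trophoblast and amnion 2 and 1 (0.3), primitive streak and mesendoderm 1 and 1 (0.839), and fibroblast and feeder 2 and 7 (0.251). Further H9 lists were FGF and ERK response 4 and 7 (0.159; median 0.02, mean -0.10), BMP response 2 and 1 (0.753), Polycomb and DNA methylation 7 and 4 (0.472; median 0.01, mean -0.01), p53 response 7 and 1 (0.132), hypoxia and glycolysis 8 and 3 (0.111), cell cycle 7 and 2 (0.161), and imprinted genes 4 and 3 (0.839; median 0.04, mean -0.05). The remaining H9 lists were genes variable among clones 3 and 0 (0.115), band 20q11.21 4 and 5 (0.699), neighbours of ZNF263 4 and 1 (0.424), histones 0 and 0 (0.548), and immediate early and heat shock 5 and 2 (0.29). Endoderm passed without clone 9-1 replicate 1 (0.0483), and neuroectoderm and neurons without wild-type replicate 2 (0.0302, camera).

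In H1, by camera with Benjamini-Hochberg adjustment, the lists that did not pass were primed pluripotency with 0 members higher and 5 lower (adjusted p = 0.168; median 0.04, mean -0.05), naive pluripotency 0 and 0 (0.777), endoderm 0 and 1 (0.965), mesoderm 1 and 1 (0.932; median -0.14, mean 0.05), neural crest 1 and 2 (0.693), NODAL and TGF-beta signalling 2 and 0 (0.435), and BMP response 1 and 1 (0.795; median 0.04, mean -0.05). Others were Polycomb and DNA methylation 2 and 1 (0.72), p53 response 0 and 3 (0.168), cholesterol synthesis 0 and 0 (0.573), cell cycle 0 and 2 (0.777), imprinted genes 0 and 2 (0.168), genes variable among clones 1 and 1 (0.626), band 20q11.21 2 and 2 (0.877), neighbours of ZNF263 0 and 0 (0.573; median 0.03, mean -0.01), and histones 0 and 0 (0.932; median -0.08 with the test's direction up). Trophoblast and amnion had too few tested members in H1. Between clones 9-D and 9-1, camera called core pluripotency (1 member higher, TERF1; adjusted p = 1.63e-07, and adjusted p = 0.307 with an estimated correlation) and fibroblast and feeder (0 members called; adjusted p = 0.00404, and adjusted p = 0.434 with an estimated correlation).

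Members of lists that did not pass, picked by the rule, had these log2 fold changes in H9: GATA2 2.06, a factor of trophoblast, TUBB3 0.64, ZNF354C 0.62, COL1A1 0.60, TIGD7 0.55, ETS1 0.54, BMP4 0.51, PFKP 0.47, PLK1 0.41, ID1 0.39, KDM2B 0.38, SESN2 0.38, FOXD3 0.38, AEN 0.36, GRB10 0.22, ZSCAN10 0.22, CCNA2 0.22, ADM -0.52, KRT7 -0.64, PDGFRB -0.79, EGR1 -0.96 and CCM2L -1.27. CSMD1 (0.86) lost its call without wild-type replicate 3 (adjusted p = 0.0597) and WNT8A (-0.67) without wild-type replicate 1 (adjusted p = 0.065, edgeR with Benjamini-Hochberg adjustment). In H1, such members were PDGFRA 0.70, ETS1 0.44, ID1 0.42, CDH2 -0.39, CDKN1A -0.47, SOX9 -0.62, BTG2 -0.66 and KRT7 -0.94.

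Other H1 members lost their call when a library was left out, with these adjusted p (edgeR with Benjamini-Hochberg adjustment; WT for wild type and KO for clone 1-10, with the replicate). They were BMP7 at -0.60 (WT 2 0.0946, KO 1 0.0856), CENPE at -0.28 (WT 1 0.0916, KO 2 0.0576), KCNQ1OT1 at -0.37 (WT 1 0.178, KO 1 0.0502), PDGFRB at -0.39 (WT 3 0.053, KO 1 0.097), LEFTY2 at 0.52 (WT 3 0.134, KO 1 0.126) and NODAL at 0.42 (WT 2 0.0506, WT 3 0.119, KO 1 0.154). The same held for TET1 at -0.20 (WT 1 0.118, WT 3 0.102, KO 2 0.0661), SOX17 at -1.59 (WT 2 0.0742, WT 3 0.0811, KO 1 0.183, KO 2 0.0878), TCERG1L at 0.35 (WT 1 0.078, WT 3 0.0813, KO 1 0.0905, KO 2 0.0618), PRC1 at -0.20 (WT 1 0.0611, WT 2 0.104, WT 3 0.14, KO 1 0.221, KO 3 0.0694) and PTPRT at -0.52 (WT 2 0.148, WT 3 0.108, KO 1 0.055, KO 2 0.121, KO 3 0.0546).

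Between clones 9-D and 9-1, 4 further genes picked by the rule passed with all libraries (edgeR with Benjamini-Hochberg adjustment) but not without some. They were TCHH at 1.49 (adjusted p = 0.0194; without 9-1 replicate 2 0.273, 3 0.116, without 9-D replicate 1 0.062, 2 0.0772, 3 0.101), ZNF283 at -0.97 (0.00879; without 9-1 replicate 1 0.0591, without 9-D replicate 2 0.0772, 3 0.112), the pseudogene PDCL3P4 at -0.83 (0.0151; without 9-1 replicate 1 0.0548, 2 0.0676, 3 0.119, without 9-D replicate 1 0.0814, 2 0.154) and SLCO1A2 at -0.70 (0.0194; without 9-1 replicate 2 0.15, 3 0.141, without 9-D replicate 1 0.0568, 2 0.107, 3 0.113).

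In the single libraries, the interferon-induced gene ISG15, chosen after its values were seen, had 319 counts in wild type, 1092 in clone 1-5 and 98 in clone 1-10, with 1 library each. No list of interferon-induced genes was tested. In the replicated comparisons IFIT1 had log2 fold changes of -0.19 in H1 (wild type 1.63 CPM, adjusted p = 0.742) and -0.09 in H9 (wild type 364 CPM, adjusted p = 0.29, edgeR with Benjamini-Hochberg adjustment).

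Genes grouped by chromosome did not pass camera with Benjamini-Hochberg adjustment. In H1, 0 of 23 chromosomes passed (lowest adjusted p = 0.985; 0 at an unadjusted p under 0.05), in H9 0 (lowest 0.179; 1 unadjusted) and between clones 9-D and 9-1 0 (lowest 0.846; 1 unadjusted). Chromosome X, chosen after its values were seen, held 542 tested genes in H9, of which 114 were called higher and 64 lower in the knockouts. Between clones 9-D and 9-1, 9 of the 47 called genes lay on X, 6 higher and 3 lower in 9-D. Camera tests a shift of a chromosome's genes in a common direction. Whether calls of both directions were concentrated on a chromosome was not tested. No other tool was run for chromosomes.

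Of the calls in H9, 2849 went the same way in both clones. Independent noise in the shared wild-type libraries does not account for this, since simulated unchanged clones reached a covariance of at most 0.0146 against 0.184. Their correlation reached at most 0.535 against 0.898. The simulations drew each gene on its own, so a state of the wild-type cultures that moves many genes together was not covered. A difference of culture history or batch in H9 alone is argued against for the genes called in both lines, of which 90% went the same way in H1. For the 3421 genes called in H9 and not in H1, 73.2% had the H9 sign in H1, where the highest of the other splits of the H1 libraries gave 66.5%, so a batch in H9 alone may explain part of them and cannot be told apart from the knockout. Both clones also share near-silent PUS7L and IRAK4, which are adjacent; descent from a common subclone was not tested, nor were editing and clonal growth as such, which all knockout clones share.

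For H9 against wild type, 1 of 84 splits of the 9 libraries called as many genes as the real 4574, and the highest other called 4. The calls thus followed the real groups more than random splits of single libraries did. The labels do not say whether libraries of a group were separate cultures, so chance differences between cultures or clones are not excluded. For the difference between the lines, 2 of 60 splits called as many as the real 1380. The highest other, 1916, was the only other split drawn that kept the real H9 groups, and it regrouped H1. Splits that did not keep them called at most 120. Such splits also break up the knockout effect within a line, so their share does not measure chance for the difference. With 3 libraries per group the other comparisons have 10 splits, too few for a share under 0.05; the real split was 1 of 10 in each, with 1827 calls in H1 (highest other 0), 4053 for clone 9-1 (0), 3619 for clone 9-D (0) and 47 between the clones (2).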
